A study of Mus musculus with 9 samples.

How the data were processed

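RNA from YAMC mouse intestinal cells was sequenced in 9 libraries: 3 of the parental line, 3 of Cdk8 knockout clone 1 and 3 of Cdk8 knockout clone 19. Per the labels' protocols, total RNA was taken with a column kit from cells in logarithmic growth at 32 °C, and libraries were made with a TruSeq RNA kit. The authors deposited 1 table of RPKM values (reads per kilobase of gene model and per megaread) for 28059 Entrez gene IDs, with 1 column per library. Per the submitters' processing notes, the tools were GSNAP, a spliced aligner, and DESeq, and the genome build was NCBIM37. The notes give no versions or roles for these tools. The gene annotation and the counting rule are not given in the sources used here, nor is whether size factors entered the RPKM values. An RPKM divides by the gene's length and by the reads of the library. For 1 gene it can be compared across libraries as far as their RNA has a like composition. A level is less reliable for very short genes, overlapping genes and near-identical gene copies.

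IDs were named through the RefSeq gene table of GRCm38 (24998 IDs) and the GENCODE M21 tables (16 IDs); 3045 IDs had no match, 978 of them among the tested genes. Because the build of these tables differs from that of the submitters, they were used for names, gene order and exon lengths only, and no coordinates are given. In genes with low values, the smallest steps between libraries gave what 1 read was worth, and from these the depth of each library was estimated. The estimates rested on 1264 genes and ran from 22.8 to 43.5 megareads. The quartiles over genes for parental replicate 1 were 38.2 and 44.2 megareads. These are estimates from the table, not read totals of the libraries, so no count test was run.

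Tests were made with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with a mean-variance trend, over the 12568 genes with an RPKM of at least 1 in at least 3 of the 9 libraries. All 9 libraries entered 1 model of group means. The contrasts were clone 1 minus parental, clone 19 minus parental, and clone 19 minus clone 1. Every adjusted p-value for a gene is from limma with Benjamini-Hochberg adjustment within a contrast, and a gene was called at an adjusted p under 0.05. Every fold change is on the log2(RPKM + 0.5) scale, which understates the change of genes with low values. The p-values measure only the spread between these libraries. The labels do not say whether the replicates were separate cultures, and separate cultures would not measure the spread between clones either. The knockout was seen in 2 clones, so 3 libraries against 3 do not replicate it.

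Of 29 gene lists with 926 entries, 923 matched the table. The lists covered the Mediator kinase module, core Mediator, PRC2 and PRC1 subunits, Hox genes, other developmental transcription factors, imprinted genes, Wnt, p53, TGF-beta, Notch and NF-kB targets, interferon-stimulated genes, antigen presentation, proliferation, cholesterol and fatty acid synthesis, glycolysis, hypoxia, immediate early genes, the integrated stress and unfolded protein response, and extracellular matrix. Markers of epithelial, mesenchymal, secretory, absorptive, immune, endothelial and neural cells completed the set. The 25 lists with at least 5 measured genes were tested with limma's camera, which compares a list with all other tested genes, at a preset inter-gene correlation of 0.01. Adjustment was by Benjamini-Hochberg over the lists within a contrast, and each test was repeated with an estimated correlation.

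The genes named in the text were set by rule: the Mediator kinase module; the 10 higher and 10 lower genes with the largest change of at least 2-fold in both clones; up to 4 genes in each direction changed at least 2-fold in 1 clone, not called in the other and different between the clones; up to 3 genes in each pattern of opposite direction; and up to 4 members of each list, preferring those called the same way in both clones. The values of 1 list member are not reported here, in the text or the plots, but it is part of the list counts and tests. These choices, the lists, the tests and the alternatives that follow were set before the data were examined. They were pseudocounts of 0.1 and 1, no filter and a filter at 3 RPKM, median-ratio scaling, quantile normalization, no mean-variance trend, array quality weights, a replicate block, only the groups compared, each library left out, a 2-fold threshold, an estimated correlation and the rotation test fry. Added after seeing the data were the subtraction, per library, of the median deviation of the 50 nearest tested genes, the list tests with each library left out, and a list of 18 mesothelial markers. Tested genes without a set of neighbours in the gene order kept their values in that subtraction.

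Data were simulated from the real means and spread over 12568 genes, with 50 genes changed at each size. For clone 1, 56% of genes changed by 0.25 on the log2 scale were recovered, 94% at 0.5, 98% at 1 and 100% at 2. For clone 19 the shares were 56%, 92%, 100% and 100%. Of the simulated calls, 2 (1.14%) for clone 1 and 8 (4.40%) for clone 19 were of unchanged genes. Far fewer genes were changed there than were called in the real data, so these shares need not hold for the real calls. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No library was left out of the main tests, and every column of the table belonged to 1 of the 9 samples.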

Results

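Gene expression was measured in YAMC cells, a mouse intestinal line that the labels place in the small intestine and that is otherwise known as a conditionally immortalized line from young adult mouse colon. The question set by the design was which transcripts change when Cdk8, the kinase of the Mediator kinase module, is knocked out by CRISPR. Parental cells, knockout clone 1 and knockout clone 19 had 3 libraries each. The estimated depth was 43.5, 27.8 and 32.5 megareads for the parental libraries, 22.8, 32.1 and 30.9 for clone 1, and 28.9, 32.8 and 24.4 for clone 19. Between 17974 and 18907 genes had a value above 0 in a library. Across tested genes, which are not independent replicates, log2 values correlated at 0.997 to 0.998 within groups, 0.963 to 0.966 between parental and clone 1, 0.967 to 0.969 between parental and clone 19, and 0.990 to 0.993 between the clones. No clone with intact Cdk8 is analysed here, so loss of Cdk8 and the isolation of a clone vary together in every comparison with the parental line.

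Cdk8 RNA (Entrez 264064) was lower in both clones but was not lost. It stood at 17.5, 17.7 and 17.5 RPKM in the parental libraries, 10.3, 11.1 and 11.6 RPKM in clone 1, and 10.5, 10.3 and 10.3 RPKM in clone 19. The log2 fold change was -0.66 ± 0.04 (SE, n = 3 against 3, adjusted p = 7.6e-08, limma) in clone 1 and -0.74 ± 0.04 (adjusted p = 3.5e-08, limma) in clone 19, with all 3 libraries of each clone below all parental ones. A CRISPR edit can abolish a protein while its RNA persists. These values go the same way as the labels, but do not show how much CDK8 protein was left. A lower call is a weak check of the labels, since 3239 of the 12568 tested genes were called lower in both clones. Which part of Cdk8 was edited cannot be read from values per gene.

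Of the other kinase module genes, Ccnc (cyclin C, the partner of CDK8) fell from 9.23 ± 0.0945 RPKM (SD, n = 3) to 7.46 ± 0.104 in clone 1 and 8.31 ± 0.184 in clone 19 (log2 fold change -0.29 and -0.14, adjusted p = 1.3e-05 and 0.0027, limma). Med13l rose from 8.66 ± 0.321 RPKM to 10.3 ± 0.326 RPKM in clone 1 and rose in clone 19 too (0.24 and 0.20, adjusted p = 1.8e-04 and 7.2e-04, limma). Cdk19, the paralog of Cdk8, measured 8.20 ± 0.258, 8.38 ± 0.184 and 9.33 ± 0.403 RPKM. It did not pass the test in clone 1 (0.03, adjusted p = 0.53, limma) and rose in clone 19 (0.18, adjusted p = 0.0027, limma). Genes next to Cdk19 were lower (medians -0.27 and -0.30), and with them subtracted Cdk19 was called higher in both clones (0.29 and 0.46, adjusted p = 1.6e-04 and 4.4e-06, limma). Med12 did not pass in either clone (-0.10 and -0.05, adjusted p = 0.11 and 0.39, limma), but was called lower in both with neighbouring genes subtracted (-0.24 and -0.17, adjusted p = 0.0035 and 0.020, limma). It was also called lower in clone 1 with median-ratio scaling (adjusted p = 0.043, limma) and without clone 1 replicate 1 (adjusted p = 0.016, limma). Med13 was not called in clone 1 (-0.14, adjusted p = 0.090, limma), but was without clone 1 replicate 1 (-0.22, adjusted p = 0.0030), with median-ratio scaling (0.043) or with array quality weights (0.036). It was called lower in clone 19 (-0.21, adjusted p = 0.019, limma), a call that ended without clone 19 replicate 1 (adjusted p = 0.0503), clone 19 replicate 2 (0.0553) or parental replicate 1 (0.0739). The tested genes next to Med13 were lower as well, by medians of -0.15 in clone 1 and -0.28 in clone 19, and with them subtracted the Med13 change in clone 19 was 0.06 (adjusted p = 0.473, limma). Of the 6 measured members, 1 rose and 2 fell in clone 1, and 2 rose and 3 fell in clone 19, with the same counts adjusted over the list alone. The list as a whole passed in neither clone (adjusted p = 0.443 and 0.552, camera).

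**Figure D1:**
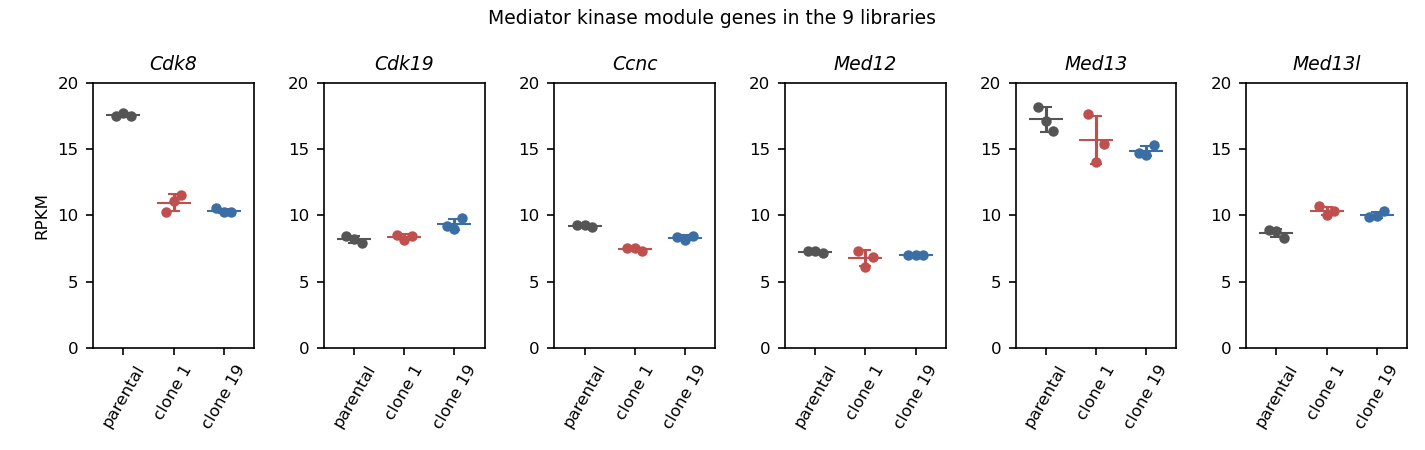
RPKM of the 6 measured Mediator kinase module genes (vertical axis, from 0) in the parental line and the 2 clones. Dots are libraries, horizontal marks are means and bars are SD (n = 3); Cdk8 lies between 17.5 and 17.7 RPKM in parental libraries and between 10.3 and 11.6 RPKM in the clones.

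In clone 1, Chl1, a neural cell adhesion molecule, rose from 0.343 ± 0.0510 RPKM to 12.9 ± 0.588 RPKM (log2 fold change 3.99 ± 0.06, SE, adjusted p = 6.6e-12, limma). Emb (embigin, a transmembrane adhesion protein) rose from 2.52 ± 0.316 to 21.3 ± 0.161 RPKM (2.85). Serpinf1, which encodes the secreted anti-angiogenic factor PEDF, fell from 38.7 ± 0.828 to 1.38 ± 0.0941 RPKM (-4.39 ± 0.05, adjusted p = 9.3e-13, limma). Ndn (necdin, imprinted) fell from 8.32 ± 0.248 to 0, 0 and 0.0577 RPKM in the 3 clone 1 libraries. By limma with Benjamini-Hochberg adjustment, 9096 of 12568 genes (72.4%) were called, 5003 higher and 4093 lower (4487 and 4499 with median-ratio scaling). Of these, 561 changed at least 2-fold, 225 higher and 336 lower. The median absolute log2 change over all tested genes was 0.22, so most of the calls were small changes against a small spread between libraries.

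In clone 19, Chl1 rose to 8.29 ± 0.508 RPKM (log2 fold change 3.38 ± 0.06, adjusted p = 2.0e-11, limma), and Lgals7, a galectin of stratified epithelia, from 3.62 ± 0.172 to 26.0 ± 0.630 RPKM (2.69 ± 0.04, adjusted p = 1.4e-11, limma). Serpinf1 fell to 1.71 ± 0.0116 RPKM (-4.15 ± 0.05, adjusted p = 1.1e-12, limma) and Sfrp1, a secreted Wnt antagonist, from 20.5 ± 0.207 to 0.930 ± 0.0555 RPKM (-3.87 ± 0.08, adjusted p = 2.9e-11, limma). Antigen presentation genes were higher in clone 19, as described with the gene groups. In all, 8675 genes (69.0%) were called by limma with Benjamini-Hochberg adjustment, 4614 higher and 4061 lower (4315 and 4373 with median-ratio scaling), and 512 changed at least 2-fold, 221 higher and 291 lower. The median absolute log2 change was 0.20.

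Changes of both clones went the same way for most called genes. The 10 named genes that rose in both were Chl1, Casp1 (the inflammatory caspase; log2 fold change 2.53 in clone 1 and 2.58 in clone 19), Lgals7 (2.41 and 2.69), Map2 (a neuronal microtubule protein; 2.32 and 2.35), Emb (2.85 and 2.23), Fndc3c1 (2.75 and 2.08), H1f2 (a linker histone; 2.27 and 2.08), Sorcs1 (a sorting receptor; 2.01 and 1.98), Nt5e (the ectonucleotidase CD73; 2.48 and 1.88) and H2bc4 (a core histone; 1.96 and 1.86). The 10 that fell were Serpinf1, Sfrp1 (-3.48 and -3.87), Sdc3 (a heparan sulfate proteoglycan; -3.46 and -3.46), Ackr3 (a chemokine scavenger receptor; -3.27 and -3.35), Aqp1 (a water channel; -3.84 and -3.27), Lrrc32 (the latent TGF-beta anchor GARP; -3.05 and -3.07), Cdsn (corneodesmosin; -3.59 and -2.91), Nsg1 (a neuronal endosomal protein; -3.42 and -2.86), Angptl2 (-2.83 and -2.99) and Apln (the peptide apelin; -2.95 and -2.75). Adjusted p-values of these 20 genes ran from 9.3e-13 to 1.6e-09 in limma. H1f2 and H2bc4 belong to families of near-identical histone genes, and reads could have been split between copies, so their levels are uncertain.

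In numbers, 7096 genes were called the same way in both clones, 3857 higher and 3239 lower (3510 and 3568 with median-ratio scaling), against 1837 and 1323 from independent lists of the same sizes. In 100 simulations of unchanged groups against the same parental libraries it was 0, which says nothing on agreement, since groups without changes give few calls. At 2-fold in both clones there were 357, 139 higher and 218 lower, against 3.96 and 7.78 from independent lists. Calls in opposite directions numbered 111 higher in clone 1 and lower in clone 19, and 131 the other way. Across genes, which are not independent replicates, the clones' log2 fold changes correlated at 0.894 with a covariance of 0.189, and 84.3% had the same sign. Simulated noise between libraries, with the parental ones shared, gave a mean correlation of 0.50 and 66.7% of the same sign. Its covariance was 0.00293, a difference of 0.186. The 3 parental libraries cannot be split into parts of at least 2, so part of the excess in calls and in the correlation may come from the shared controls. The covariance difference leaves out the share of noise between libraries, but not that of a deviation common to all 3 parental libraries. Neighbouring genes shifted together: 1374 tested genes in clone 1 and 1632 in clone 19 lay in stretches of 50 neighbours whose median deviated more than in any of 20 shuffled gene orders, by at most -0.55 and -0.47 on the log2 scale.

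**Figure D2:**
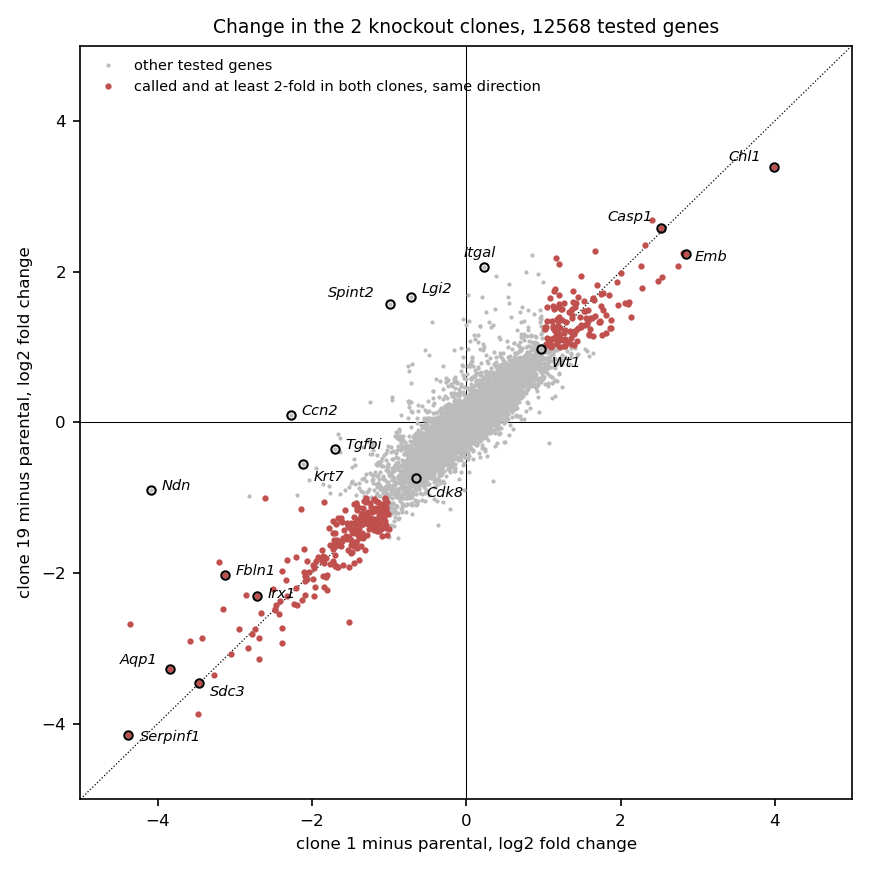
Log2 fold change against parental cells in clone 1 (horizontal axis) and clone 19 (vertical axis) for the 12568 tested genes; red dots are the 357 genes called and changed at least 2-fold in both clones in 1 direction, and open circles carry gene names. The dots lie along the dotted line of equal change (correlation 0.894), while Ndn, Ccn2, Spint2 and Lgi2 lie far from it.

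Cholesterol synthesis genes rose in both clones. Of the 23 measured, 21 rose and 1 fell in clone 1, and 21 rose and 0 fell in clone 19, with 1 and 2 not passing. Counts adjusted over the list alone were the same. Cyp51 (lanosterol demethylase) rose from 24.4 ± 1.14 to 43.1 ± 0.878 and 52.1 ± 2.65 RPKM (log2 fold change 0.81 and 1.08). Msmo1 rose from 37.2 to 60.4 and 78.0 RPKM (0.69 and 1.06). Srebf2, the transcription factor that drives this pathway, rose from 51.0 to 84.8 and 101 RPKM (0.73 and 0.98). The medians were 0.56 and 0.67 (camera adjusted p = 4.0e-05 and 3.4e-07). These calls were lost with an estimated correlation (adjusted p = 0.38 and 0.18 with an estimated correlation). Fatty acid synthesis genes, by contrast, went both ways. Of 20 measured, 11 rose and 4 fell in clone 1 and 9 rose and 6 fell in clone 19, with 5 not passing in each and the same counts adjusted over the list alone (camera adjusted p = 0.318 and 0.532). Fads2, a fatty acid desaturase, rose from 95.8 to 148 and 200 RPKM (0.62 and 1.06). Dgat2, which makes triglyceride, fell from 3.27 to 1.27 and 1.55 RPKM (-1.09 and -0.88).

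Antigen presentation genes rose in clone 19. Of the 26 measured, 24 rose, 1 fell and 1 did not pass in clone 19, against 9, 9 and 8 in clone 1, with the same counts adjusted over the list alone. H2-Aa, an MHC class II chain, rose from 102 ± 0.196 RPKM to 138 ± 2.85 in clone 1 and 222 ± 16.4 in clone 19 (log2 fold change 0.43 and 1.11). H2-Eb1 rose from 52.6 to 62.0 and 105 RPKM (0.23 and 1.00), Cd74 (the invariant chain) from 408 to 631 and 689 RPKM (0.63 and 0.76), and Psme2 (a proteasome activator) from 54.0 to 68.6 and 75.2 RPKM (0.34 and 0.48). With neighbouring genes subtracted the rise in clone 1 was larger for H2-Aa (0.72) and H2-Eb1 (0.54). The list passed in clone 19 (median 0.21, camera adjusted p = 5.9e-06; adjusted p = 0.69 with an estimated correlation) but not in clone 1 (0.01, adjusted p = 0.922). With the median of the 50 neighbouring genes subtracted, an alternative added after seeing the data, it passed in clone 1 too (median 0.16, camera adjusted p = 0.0018). In that alternative 18 rose and 3 fell in clone 1, and 22 rose and 0 fell in clone 19. Interferon-stimulated genes went both ways. Of 53 measured, 24 rose, 22 fell and 7 did not pass in clone 1, and 25, 17 and 11 in clone 19 (24 and 22, and 25 and 18, adjusted over the list alone; camera adjusted p = 0.84 and 0.565). Ifi27l2a rose from 22.8 to 54.7 and 65.7 RPKM (1.24 and 1.51) and Rsad2 (viperin) from 5.06 to 12.3 and 10.5 RPKM (1.20 and 0.99). Tgtp1, an interferon-induced GTPase, fell from 11.6 to 4.88 and 4.99 RPKM (-1.17 and -1.14).

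Immediate early genes fell in both clones. Of 26 measured, 19 fell and 4 rose in clone 1 and 15 fell and 4 rose in clone 19, with 3 and 7 not passing and the same counts adjusted over the list alone. Fosl1 (an AP-1 subunit) fell from 34.8 to 17.3 and 14.5 RPKM (log2 fold change -0.98 and -1.23), Junb from 44.2 to 23.9 and 23.3 RPKM (-0.87 and -0.91) and Klf2 from 10.1 to 5.50 and 5.40 RPKM (-0.82 and -0.85). Dusp5, a phosphatase of ERK, rose from 9.03 to 16.6 and 19.4 RPKM (0.85 and 1.06). Genes next to Junb were lower too (medians -0.52 and -0.43), and with them subtracted its change was -0.39 and -0.48. The list passed in both (camera adjusted p = 9.4e-04 and 0.021; adjusted p = 0.62 and 0.75 with an estimated correlation). In clone 19 the call ended with neighbouring genes subtracted (adjusted p = 0.25). Genes of the integrated stress and unfolded protein response fell in clone 1: of 30 measured, 18 fell, 9 rose and 3 did not pass in clone 1 (camera adjusted p = 0.017; adjusted p = 0.62 with an estimated correlation), and 18, 8 and 4 in clone 19, where the list did not pass (adjusted p = 0.095; 0.0148 with neighbouring genes subtracted). Counts over the list alone were the same. Vldlr, a lipoprotein receptor also induced by ATF4, fell from 4.76 to 1.57 and 1.59 RPKM (-1.34 and -1.34). Ddit4, an inhibitor of mTORC1, fell from 11.2 to 4.13 and 6.48 RPKM (-1.33 and -0.74), and Slc7a11, the cystine transporter, from 3.98 to 1.65 and 1.95 RPKM (-1.06 and -0.87). Xbp1, of the unfolded protein branch, rose from 35.0 to 71.4 and 60.2 RPKM (1.02 and 0.77; 0.56 and 0.44 with neighbouring genes subtracted).

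Epithelial markers were few but mostly higher in the clones. Of the 43 listed, 13 were measured, and in each clone 10 rose, 2 fell and 1 did not pass, with the same counts adjusted over the list alone. Of those that rose, 3 (Krt8, Krt18 and Krt19) are mesothelial markers as well. Krt19 rose from 101 to 174 and 183 RPKM (log2 fold change 0.78 and 0.85), Lsr (a tricellular junction protein) from 13.6 to 26.1 and 28.7 RPKM (0.92 and 1.05) and Dsp (desmoplakin) from 0.861 to 1.46 and 2.39 RPKM (0.53 and 1.08). Krt7 fell from 22.1 to 4.74 and 14.9 RPKM (-2.11 and -0.56). The list passed in both clones (camera adjusted p = 0.049 and 0.012; adjusted p = 0.62 and 0.33 with an estimated correlation). In clone 1 the call ended without parental replicate 2 (adjusted p = 0.0597), clone 1 replicate 1 (0.0633) or clone 19 replicates 1, 2 or 3 (0.0552, 0.0582 and 0.0527). Mesenchymal and fibroblast markers went both ways, with more lower than higher. Of 34 measured, 20 fell, 13 rose and 1 did not pass in clone 1, and 21, 10 and 3 in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.262 and 0.095). Fbln1 (fibulin) fell from 3.97 to 0.0124 and 0.600 RPKM (-3.13 and -2.03), Col5a1 from 59.9 to 18.5 and 15.5 RPKM (-1.66 and -1.92), Snai1 from 6.56 to 1.85 and 1.42 RPKM (-1.59 and -1.89) and Col6a3 from 8.35 to 2.21 and 2.5 RPKM (-1.71 and -1.56). Of 35 extracellular matrix and adhesion genes, 20 rose, 10 fell and 5 did not pass in clone 1, and 19, 12 and 4 in clone 19 (20 and 11, and 20 and 12, adjusted over the list alone; camera adjusted p = 0.318 and 0.532). Nid1 (nidogen) fell from 54.2 to 15.2 and 11.2 RPKM (-1.80 and -2.22), and the collagenase Mmp13 rose from 4.64 to 14.8 and 12.5 RPKM (1.58 and 1.34).

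Markers of other cells were sparse. Of 28 secretory intestinal markers, 1 was measured, Dclk1, which fell (log2 fold change -0.29 and -0.35; -0.67 and -0.77 with neighbouring genes subtracted), and of 33 absorptive ones 3 were measured, among them Mttp (0.67 and 0.51; 0.35 and 0.20 with neighbouring genes subtracted) and Emp1 (-0.23 and -0.44), both called in both clones. Of 25 immune cell markers 2 were measured: Cd68 rose in clone 19 (0.37, adjusted p = 0.0050, limma; 0.20, adjusted p = 0.0738, with neighbouring genes subtracted) and did not pass in clone 1 (0.22, adjusted p = 0.062). In clone 1 Cd68 was called higher with quantile normalization (adjusted p = 0.022, limma), array quality weights (0.033), only the groups compared (0.017), or without clone 19 replicate 1 (0.030) or 3 (0.019). Cd14 passed in neither (-0.10 and -0.14), but was called lower in clone 1 without clone 1 replicate 3 (adjusted p = 0.045, limma). Of 7 measured endothelial markers, 4 rose, 2 fell and 1 did not pass in each clone, with the same counts adjusted over the list alone (camera adjusted p = 0.443 and 0.532). Esam rose from 20.2 to 47.3 and 40.9 RPKM (1.21 and 1.00) and Kdr fell from 1.63 to 0.735 and 0.671 RPKM (-0.78 and -0.86). Of 4 measured neural and glial markers, 1 rose and 2 fell in clone 1 and 1 rose and 3 fell in clone 19, with Tubb3 lower in both (-0.88 and -0.75).

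Among chromatin regulators and their usual targets, changes went both ways. Of 11 PRC2 genes, 7 fell, 3 rose and 1 did not pass in clone 1, and 4, 3 and 4 in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.277 and 0.565). Phf19, a PRC2 recruiter, fell from 2.13 to 0.678 and 0.466 RPKM (log2 fold change -1.16 and -1.45) and Aebp2 from 24.1 to 17.7 and 18.4 RPKM (-0.43 and -0.38). Of 19 PRC1 genes, 5 rose, 6 fell and 8 did not pass in clone 1, and 6, 7 and 6 in clone 19 (4 and 6, and 6 and 7, adjusted over the list alone; camera adjusted p = 0.751 and 0.742). Pcgf5 rose (0.76 and 0.83) and Bmi1 fell (-0.41 and -0.37; -0.27 and -0.19 with neighbouring genes subtracted). Of 29 Hox genes, 7 rose and 11 fell in clone 1 and 7 rose and 13 fell in clone 19 (7 and 10, and 7 and 13, adjusted over the list alone; camera adjusted p = 0.609 and 0.483), with Hoxb9 lower (8.05 to 2.01 and 3.95 RPKM, -1.77 and -0.94) and Hoxd11 higher (0.56 and 0.54). Of 43 other developmental transcription factors, 17 rose and 15 fell in clone 1 and 12 rose and 19 fell in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.981 and 0.532). Irx1 fell from 8.16 to 0.817 and 1.26 RPKM (-2.72 and -2.30), Lhx6 also fell (-1.60 and -1.54), and Wt1 rose from 80.1 ± 2.14 to 158 ± 1.10 and 158 ± 2.12 RPKM (0.97 and 0.98). Of 22 imprinted genes, 10 rose and 5 fell in clone 1 and 11 rose and 6 fell in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.751 and 0.532). Igf2 fell from 6.04 to 0.752 and 0.486 RPKM (-2.39 and -2.73), and Snrpn rose (1.59 and 0.88) together with Snurf (1.65 and 0.92), which overlaps it and so cannot be read apart from it. Of 26 core Mediator genes, 11 rose and 8 fell in clone 1, and 7 rose and 6 fell in clone 19 (camera adjusted p = 0.981 and 0.790). Adjusted over the list alone the counts were 11 and 9, and 7 and 6. With neighbouring genes subtracted, 11 rose and 2 fell in clone 1, and 10 and 2 in clone 19 (camera adjusted p = 0.24 and 0.25). Med31 was higher (0.38 and 0.46). Med16 was called lower (-0.39 and -0.40) along with its neighbours, and was no longer called with these subtracted (-0.01 and -0.02, adjusted p = 0.843 and 0.653, limma).

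Signalling target lists passed in neither clone. Of 13 Wnt/beta-catenin targets, 8 rose and 4 fell in clone 1 and 5 rose and 7 fell in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.84 and 0.532). With neighbouring genes subtracted, 3 rose and 5 fell in clone 1, and 4 and 7 in clone 19 (camera adjusted p = 0.68 and 0.25). Ccnd1 (cyclin D) fell from 130 to 69.8 and 68.3 RPKM (log2 fold change -0.90 and -0.93), Sox9 from 1.44 to 0.0861 and 0.286 RPKM (-1.73 and -1.31), and Bmp4 rose (0.45 and 0.59). Of 24 TGF-beta and SMAD targets, 8 rose and 13 fell in clone 1 and 8 rose and 10 fell in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.251 and 0.532; 0.0464 in clone 1 with neighbouring genes subtracted). Col1a1 fell from 375 to 195 and 151 RPKM (-0.94 and -1.30) and Ltbp2 from 1.25 to 0.0502 and 0.0970 RPKM (-1.67 and -1.56). Of 6 Notch targets, 2 rose and 4 fell in clone 1 and 2 rose and 3 fell in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.73 and 0.576). Notch1 fell (-0.99 and -1.19; -0.63 in clone 1 with neighbouring genes subtracted) and Jag1 rose (0.74 and 1.09). Of 27 NF-kB targets and inflammatory mediators, 12 rose and 10 fell in clone 1 and 15 rose and 9 fell in clone 19 (13 and 10, and 15 and 9, adjusted over the list alone; camera adjusted p = 0.981 and 0.532). Il33 rose from 3.36 to 10.3 and 14.3 RPKM (1.49 and 1.94) and Il1rn, the interleukin receptor antagonist, from 2.76 to 10.1 and 11.0 RPKM (1.70 and 1.82). Nos2 fell from 3.20 to 0.431 and 0.376 RPKM (-1.99 and -2.08).

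Growth and metabolism lists also went both ways. Of 47 proliferation and cell cycle genes, 28 rose and 14 fell in clone 1 and 23 rose and 12 fell in clone 19 (28 and 14, and 23 and 13, adjusted over the list alone; camera adjusted p = 0.277 and 0.532). Rrm2 rose from 119 to 188 and 184 RPKM (log2 fold change 0.66 and 0.63), while Ccne1 (-0.57 and -0.75) and E2f1 (-0.66 and -0.39) fell. Of 23 p53 targets, 15 rose and 6 fell in clone 1 and 13 rose and 6 fell in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.251 and 0.483), with Perp (1.01 and 0.73) and Btg2 (0.70 and 0.97) higher. Of 26 glycolysis genes, 9 rose and 10 fell in clone 1 and 8 rose and 11 fell in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.84 and 0.532). Pfkl, a phosphofructokinase, fell from 21.3 to 8.77 and 8.58 RPKM (-1.23 and -1.26), and the lactate transporters Slc16a3 (46.7 to 113 and 107 RPKM, 1.27 and 1.19) and Slc16a1 (65.1 to 118 and 128 RPKM, 0.85 and 0.97; 0.56 in clone 1 with neighbouring genes subtracted) rose. Of 19 hypoxia genes, 5 rose and 9 fell in clone 1 and 5 rose and 10 fell in clone 19, with the same counts adjusted over the list alone (camera adjusted p = 0.443 and 0.532). Plod2 rose (0.99 and 0.61) and Bnip3 fell (-1.04 and -1.04). A list's median, mean and camera direction differed in sign for 6 lists in clone 1, 3 in clone 19 and 4 between the clones, with adjusted p-values of 0.532 or more.

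The direct comparison of the clones asked which changes depend on the clone. Ccn2, which encodes connective tissue growth factor, fell from 11.1 ± 0.736 RPKM to 1.89 ± 0.146 RPKM in clone 1 and measured 12.0 ± 1.34 RPKM in clone 19 (0.10, adjusted p = 0.28; 0.19, adjusted p = 0.033, without clone 19 replicate 2; 0.39, adjusted p = 0.0021, with neighbouring genes subtracted; log2 difference between the clones 2.38 ± 0.08, adjusted p = 6.2e-08, limma). Spint2, a protease inhibitor of epithelia, fell to 0.503 RPKM in clone 1 and rose to 5.41 RPKM in clone 19 from 1.47 RPKM (2.56, adjusted p = 2.0e-07). Lgi2 (2.37) and Ankrd1 (1.51) split in the same way. Ndn, almost lost in clone 1, was higher in clone 19 than in clone 1 (3.18), as were Cxcl9 (1.51) and Tgfbi (1.35). With neighbouring genes subtracted, Ndn was lower than in parental cells in both clones (-4.18 in clone 1 and -0.95 in clone 19). Col1a2 rose in clone 1 (63.7 to 90.3 RPKM) and fell in clone 19 (53.3 RPKM; difference -0.76, adjusted p = 1.9e-06), as did an unnamed gene with nearly the same values (Entrez 100862129; -0.75), whose reads cannot be told from those of Col1a2 here, and Gstm4 (-0.66). The Gstm4 fall in clone 19 (-0.27, adjusted p = 0.033) was not called without clone 19 replicate 1 or 3 (adjusted p = 0.102 and 0.0558) or parental replicate 2 or 3 (0.0786 and 0.135), with no filter (0.0584) or with quantile normalization (0.107), and was -0.56 with neighbouring genes subtracted. Its rise in clone 1 (0.39) was not called with neighbouring genes subtracted (0.11, adjusted p = 0.329). Genes changed at least 2-fold in clone 19, not called in clone 1 and different between the clones numbered 9 higher and 2 lower. The integrin gene Itgal rose from 0.327 to 2.94 RPKM (difference 1.83), Pgc (pepsinogen C) from 0.283 to 2.0 RPKM (1.66), the acute-phase gene Saa3 from 49.6 to 129 RPKM (1.40) and the calcium channel gene Cacna1g from 1.00 to 3.30 RPKM (1.30). In clone 1, Itgal (0.23) was called higher with quantile normalization (0.68, adjusted p = 1.0e-04, limma), a pseudocount of 0.1 (adjusted p = 0.027), no mean-variance trend (0.038), or without parental replicate 1 (0.026) or clone 19 replicate 2 (0.042). Pgc was called higher there with quantile normalization (0.49, adjusted p = 0.0053, limma). Snora75 and Snord95 were the 2 lower; Snora75 was called lower in clone 1 too with only the groups compared (adjusted p = 0.042, limma). For clone 1 the numbers were 1 higher, Snord64, and 4 lower, Ccn2, Snord1b, Mir3074-1 and Mir24-1. Mir24-1 was called lower in clone 19 too without clone 1 replicate 1 (-0.31, adjusted p = 0.026, limma) or with only the groups compared (adjusted p = 0.012). These small RNA genes are too short for a reliable RPKM, and the Snord64 rise in clone 1 (1.07, adjusted p = 0.045) was not called without clone 1 replicate 1 (0.0588) or 3 (0.179), clone 19 replicate 3 (0.0508) or any parental replicate (0.0625, 0.0903 and 0.109). It was not called with a pseudocount of 0.1 (0.149), no filter (0.106), median-ratio scaling (0.050), no trend (0.074) or neighbouring genes subtracted (0.062) either.

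By limma with Benjamini-Hochberg adjustment, 5404 genes (43.0%) differed between the clones, 2327 higher and 3077 lower in clone 19 (2603 and 2712 with median-ratio scaling), of which 58 differed at least 2-fold, 56 higher and 2 lower. The 2-fold count was 89 with a pseudocount of 0.1, 32 with a pseudocount of 1 and 34 with a filter at 3 RPKM. Of the 25 lists, 3 differed. Interferon-stimulated genes also did with neighbouring genes subtracted (camera adjusted p = 0.028, against 0.172), and extracellular matrix and adhesion genes without clone 1 replicate 2 (0.039, against 0.156). Antigen presentation genes were higher in clone 19 (21 of 26 higher and 2 lower, 21 and 3 adjusted over the list alone; median 0.28, camera adjusted p = 4.7e-12, and adjusted p = 0.45 with an estimated correlation). With neighbouring genes subtracted 15 were higher and 1 lower (median 0.16, camera adjusted p = 5.5e-06). The 70 tested neighbours of the H2 genes, outside the list, were higher in clone 19 too, by a median of 0.22 (95% interval 0.16 to 0.27). Cholesterol synthesis genes were higher in clone 19 (13 of 23 higher and 2 lower, the same adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.45 with an estimated correlation). Genes of the integrated stress and unfolded protein response were also higher in clone 19 (16 of 30 higher and 6 lower, 17 and 6 adjusted over the list alone; camera adjusted p = 0.0028, and adjusted p = 0.64 with an estimated correlation). The stretches of neighbouring genes that shifted between the clones covered 1920 tested genes, by at most 0.31.

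**Figure D3:**
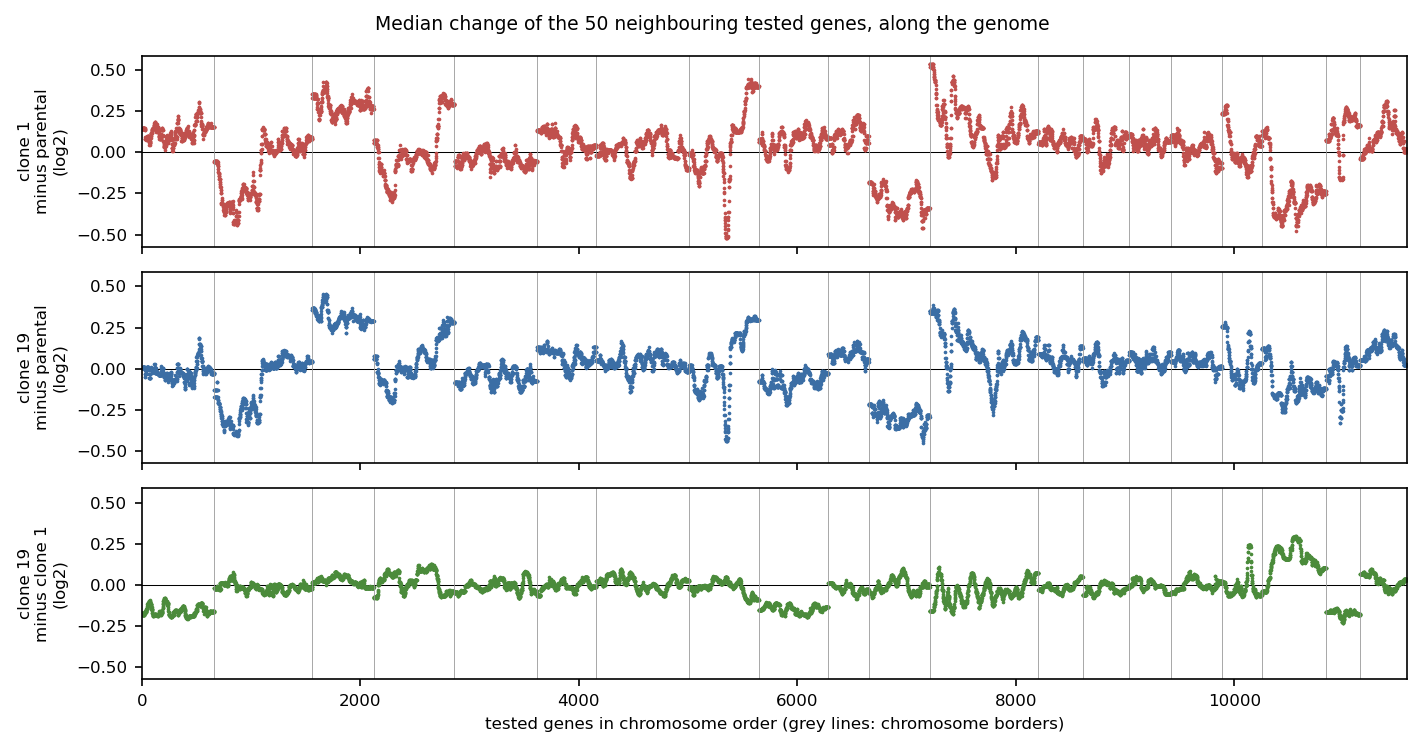
Median log2 change of the 50 tested genes nearest to each tested gene (vertical axes), with genes in chromosome order along the horizontal axis and grey lines at chromosome borders, for clone 1 and clone 19 against parental cells and for clone 19 against clone 1. Several long stretches deviate from 0 in both clones, by at most -0.55 in clone 1 and -0.47 in clone 19.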

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

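The results here are differences between the clones, by the test of the difference itself. Of the tests given, those of the shared parental libraries, of neighbouring genes over all tested genes, of immune cells and of fibroblast-like cells were chosen after their results had been seen, as were the neighbour subtraction and the list tests with a library left out.

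Between the clones, 5404 genes differed. The differences (log2, clone 19 minus clone 1) of genes named in the text that passed were as follows. Of genes changed in both clones, Chl1 differed by -0.61, Emb by -0.63, Fndc3c1 by -0.67, H1f2 by -0.19, Nt5e by -0.60, Lgals7 by 0.28, Serpinf1 by 0.24, Sfrp1 by -0.39, Aqp1 by 0.57, Cdsn by 0.68, Nsg1 by 0.56 and Angptl2 by -0.16. Of genes called in 1 clone or in opposite directions, the values were Ccn2 2.38, Itgal 1.83, Pgc 1.66, Saa3 1.40, Cacna1g 1.30, Snord64 -1.34, Snord1b 1.43, Mir3074-1 0.83, Mir24-1 0.91, Snora75 -1.0, Snord95 -0.94, Gstm4 -0.66, Col1a2 -0.76, the unnamed gene that tracks it (Entrez 100862129) -0.75, Spint2 2.56, Ankrd1 1.51 and Lgi2 2.37. In the regulator lists, Cdk19 differed by 0.15, Ccnc by 0.15, Med1 by -0.19, Phf19 by -0.28, Phf1 by 0.46, Pcgf5 by 0.0764, Hoxb9 by 0.82, Irx1 by 0.41, Six3 by -0.30, Igf2 by -0.34, Ndn by 3.18, Snurf by -0.73 and Snrpn by -0.71. In the signalling lists, Sox9 differed by 0.42, Bmp4 by 0.14, Fzd7 by -0.20, Ifi27l2a by 0.26, Rsad2 by -0.21, Cxcl9 by 1.51, Tgfbi by 1.35, Jag1 by 0.34, Il33 by 0.45, Fosl1 by -0.25 and Dusp5 by 0.22. In the growth and metabolism lists, the values were Ccne1 -0.17, E2f1 0.27, Psrc1 -0.23, Perp -0.27, Btg2 0.27, Pmaip1 0.49, Cyp51 0.27, Msmo1 0.37, Srebf2 0.25, Dgat2 0.21, Fads2 0.43, Slc16a3 -0.0807, Aldoc 0.29, Slc16a1 0.12, Ddit4 0.59, Plod2 -0.39, Egln3 0.26 and Xbp1 -0.24. In the antigen presentation, marker and matrix lists, they were H2-Aa 0.68, Cd74 0.13, H2-Eb1 0.76, Psme2 0.13, Krt7 1.55, Lsr 0.13, Dsp 0.56, Fbln1 1.10, Col1a1 -0.36, Col5a1 -0.25, Snai1 -0.30, Emp1 -0.20, Esam -0.21, Flt4 -0.36, Flt1 -0.22, Tubb3 0.12, Prph 0.43, Nid1 -0.42, Mmp13 -0.23 and Col18a1 0.37. The 3 lists that differed were antigen presentation (adjusted p = 4.7e-12), cholesterol synthesis (adjusted p = 0.0016) and the integrated stress and unfolded protein response (adjusted p = 0.0028). None of the 3 passed with an estimated correlation (adjusted p = 0.45, 0.45 and 0.64).

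Some of these calls, all from limma with Benjamini-Hochberg adjustment, ended when 1 library was left out; the adjusted p without it follows. Without clone 1 replicate 1 these were Angptl2 (0.125), Mir3074-1 (0.112), Snora75 (0.112), Snord95 (0.0880), Pcgf5 (0.111), Six3 (0.0577), Rsad2 (0.0931), Psrc1 (0.0520) and Flt1 (0.0717). Without clone 1 replicate 2 they were Angptl2 (0.0774), Mir3074-1 (0.0860), Phf19 (0.0949), Pcgf5 (0.0550), Rsad2 (0.0538), Dgat2 (0.148), Slc16a3 (0.0800) and Snai1 (0.0602). Without clone 1 replicate 3 they were Angptl2 (0.0624), Snord64 (0.109), Snora75 (0.10), Snord95 (0.101), Pcgf5 (0.101), Six3 (0.0535), Psrc1 (0.0815), Dgat2 (0.0662), Snai1 (0.112), Flt1 (0.0622) and Mmp13 (0.0584). Without clone 19 replicate 1 they were Angptl2 (0.165), Snord64 (0.0829), Mir3074-1 (0.106), Snora75 (0.0720), Snord95 (0.125), Phf19 (0.0506), Pcgf5 (0.0692), Six3 (0.0743), Rsad2 (0.0767), Psrc1 (0.0754), Dgat2 (0.0876), Slc16a3 (0.0696), Snai1 (0.105), Flt1 (0.0883) and Mmp13 (0.0597). Leaving out clone 19 replicate 2 ended the call of Pcgf5 (0.154). Leaving out clone 19 replicate 3 ended those of Cdk19 (0.0573), Angptl2 (0.104), Mir3074-1 (0.0908), Snora75 (0.0838), Phf19 (0.0897), Six3 (0.0702), Rsad2 (0.113), Psrc1 (0.0817), Dgat2 (0.159), Slc16a3 (0.0637) and Snai1 (0.0560). The parental libraries enter through the shared spread: leaving out replicate 1, 2 or 3 ended the calls of Angptl2 (0.0680, 0.0675 and 0.0706), Snora75 (0.0537, 0.0538 and 0.0547) and Dgat2 (0.0628, 0.0613 and 0.0639), and leaving out replicate 2 that of Pcgf5 (0.0588). With neighbouring genes subtracted the calls of Fzd7 (-0.04, adjusted p = 0.492), Esam (-0.08, adjusted p = 0.103) and Mmp13 (-0.10, adjusted p = 0.252) ended. Those of Psme2 (0.11, adjusted p = 0.0503), Angptl2 (-0.16, adjusted p = 0.0717), Snora75 (-0.86, adjusted p = 0.0804), Dgat2 (0.21, adjusted p = 0.0509) and Snai1 (-0.27, adjusted p = 0.0555) ended too, with differences about as large as before. Calls that stayed but moved by over 1.5 times include those of Cd74 (0.29), H2-Aa (0.45), Phf1 (0.26), Xbp1 (-0.12), Plod2 (-0.21), Btg2 (0.45), Cdsn (0.43), Tubb3 (0.21), Pcgf5 (0.12) and Slc16a3 (-0.15). The other alternatives ended calls only of genes named in this paragraph. Leaving out clone 19 replicate 1 brought the Snord64 difference to -0.79, and leaving out clone 19 replicate 3 that of Snora75 to -0.51.

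Regrouping the libraries bears on the counts of called genes. For clone 1 against parental the real split gave 9096 genes and was the 1 of 10 splits with so many (highest other 0), for clone 19 against parental 8675 (1 of 10, highest other 0), and for clone 19 against clone 1 5404 (1 of 10, highest other 0). With 10 splits no share under 0.05 can be reached. For genes called the same way in both clones, 1 of 100 drawn assignments of the 9 libraries, the real one, reached 7096. The highest other assignment gave 6380, which points to a structure of the samples. The 5 drawn assignments that kept the 3 parental libraries together reached up to 6380, and the 94 that split them at most 475. Libraries within a group were nearly alike, so mixing parental with clone libraries widens the spread and loses calls, whatever set the groups apart. Shuffling single libraries therefore cannot decide whether chance differences between the parental line and the clones gave the count.

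Most called genes moved the same way in both clones. Noise between libraries, with the parental ones shared, is argued against as the whole source by the covariance of the fold changes. This covariance was 0.189, against a highest simulated value of 0.00377. The simulation held no deviation common to all parental libraries, which would enter both comparisons. It therefore cannot decide on such a deviation, which remains open. Gene length was hardly related to the fold changes (Spearman correlation 0.0121 and -0.0523, over the 86.6% of tested genes with a length), which argues against it as the source; removing its trend moved the clones' correlation only from 0.899 to 0.900 and is no further test. Shifts of neighbouring genes as the whole source are argued against by a correlation of 0.894 and a covariance of 0.168 after their subtraction. These values are over the 11581 of 12568 tested genes with a set of neighbours in the gene order. The correlation was 0.894 before, and simulated noise with the parental libraries shared gave 0.50. For the genes changed at least 2-fold in both clones, copy number of neighbouring genes was not decided. Of the 335 of 357 that had such a set, 83.9% (281, 95% Wilson interval 79.6 to 87.4%) stayed so after subtraction. That share is above the bound set beforehand, 80%, but the bound lies inside the interval. The interval treats the genes as independent, which neighbours that shift together are not. Loss of Cdk8 and the history of single-cell cloning and selection both remain open as causes, untested, because each clone has both.

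Antigen presentation genes were higher in clone 19 than in clone 1. Immune cells in the clone 19 cultures are argued against, since the 25 immune markers rose by 0.735 RPKM in sum, 0.0594% of the 1238 RPKM by which the antigen presentation genes rose, and Ptprc, Laptm5 and Coro1a reached at most 0.00601, 0.0375 and 0.338 RPKM. The bound for that test was rewritten after 3 of the markers, Cd68, Cd14 and Fcgr3, had been seen to reach 1 RPKM. Copy number of the region with the H2 genes remains open as a part of the pattern. The 70 neighbouring genes were higher in clone 19 by a median of 0.22 (0.16 to 0.27). The 12 H2 genes were higher by 0.46, 11 of them called, and the 14 members elsewhere by 0.15 (0.03 to 0.23), 10 of them called. Both intervals come from resampling genes, which are not independent replicates. Against parental cells, the genes around H2-Aa had a median change of -0.24 in clone 1 and -0.06 in clone 19. A difference that arose in cloning was not tested.

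More mesenchymal and fibroblast markers fell than rose in both clones. Fewer fibroblast-like cells in the clone cultures would lower all of the abundant markers only if the other cells made none of them. Values for whole cultures cannot show that, so the test cannot decide on such cells. Of the 16 markers with at least 50 RPKM, 9 had a log2 fold change above 0 in a clone. At least 2-fold falls in a clone numbered 2, Col5a1 in both and Col1a1 in clone 19, so the markers did not fall as a block. Col3a1 (152 to 194 and 183 RPKM) and Fn1 (211 to 295 and 299 RPKM), chosen after their values were seen, rose in both clones. A change of regulation within the cells is a hypothesis that was not tested.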

How the results depend on the processing

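The subtraction of neighbouring genes and the list tests with a library left out were chosen after the data were seen; the other alternatives were planned. At an adjusted p under 0.05 alone, the alternatives called 7990 to 10226 genes in clone 1, 7613 to 9659 in clone 19, 4152 to 5402 between the clones and 6273 to 7685 the same way in both, against 9096, 8675, 5404 and 7096. At 2-fold as well, the counts were 561 for clone 1, 512 for clone 19, 58 between the clones and 357 the same way in both, since most changes were small. With neighbouring genes subtracted they were 8333, 7947, 4152 and 6484, of which 6858, 6651, 3494 and 5193 were also main calls. Cdk8 was called lower at an adjusted p under 0.05 in each refit, but its change is under 2-fold. Of 431 results for single named genes, 371 kept their direction and side of the threshold under every alternative tried, 30 lost and 30 gained a call at least once, and 1 reversed: Med13 in clone 19 with neighbouring genes subtracted (0.0626, adjusted p = 0.473, limma), where the genes around it were lower. With an estimated correlation camera called 0 lists in clone 1, 0 in clone 19 and 0 between the clones (1, 2 and 2 of 25 at an unadjusted p under 0.05), against 4, 4 and 3 at the preset correlation; the rotation test fry, which does not compare a list with other genes, called 16, 20 and 16. With neighbouring genes subtracted camera called 6, 4 and 4. A fit with the replicate number as a block called 9037, 8574 and 5169 genes, with 7023 the same way, and ended the call of epithelial markers in clone 1 (adjusted p = 0.0516) and, between the clones, those of Angptl2, Snord95 and Pcgf5 (adjusted p = 0.056, 0.055 and 0.051, limma). The numbers do not pair the samples: same-numbered libraries correlated at -0.0353 to 0.123 (1 of 9 pairs over 0.1), other pairs at -0.14 to 0.0806, and 2 of the 9 libraries correlated best with their own number. The cause of the other moves was not tested. Depth limits genes near 1 RPKM, where 1 RPKM of a gene of 2 kilobases is an estimated 45.7 to 86.9 reads.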

Other observations

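Of the tests in this part, that of mesothelial markers was set before their levels were read, but the list was written after the data had been examined, when Wt1 and several keratins had been seen; the tests without these members were added after the results, and the neighbouring gene stretches were examined after the data were seen.

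Mesothelial markers were abundant in this intestinal line and rose further in the clones. The mesothelium is the cell layer that covers the gut and lines the body cavity. Upk3b stood at 355 ± 2.58 RPKM in parental cells, 666 ± 15 in clone 1 and 655 ± 4.24 in clone 19 (log2 fold change 0.91 and 0.88), and Upk1b at 363, 645 and 703 RPKM (0.83 and 0.95). Lrrn4 rose from 55.6 to 170 and 146 RPKM (1.6 and 1.38), Gpm6a from 80.8 to 179 and 192 RPKM (1.14 and 1.24), and Rspo1 from 6.59 to 16.2 and 19.6 RPKM (1.23 and 1.5). Msln (mesothelin) fell from 111 to 82.6 and 101 RPKM (-0.43 and -0.14), and Calb2 was listed at 0 in all 9 libraries. Of the 16 measured, 14 rose and 2 fell in clone 1 and 15 rose and 1 fell in clone 19, with medians of 0.81 and 0.82. Without Wt1, Krt8, Krt18 and Krt19, seen before the list was written, 10 of 12 rose and 2 fell in clone 1, and 11 rose and 1 fell in clone 19. Their medians were 0.83 and 0.82 (unadjusted camera p = 1.3e-04 and 1.3e-06, and 0.015 and 0.0054 with an estimated correlation, for this 1 list tested alone). Leaving out the seen members does not undo that the list was written after the data had been examined. These p-values are therefore no independent test. Between the clones, 6 of the 16 were higher and 5 lower in clone 19, and of the 12 it was 6 and 3.

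Classical intestinal epithelial genes were near the floor. Cdh1 (E-cadherin) measured 0.549, 0.521 and 1.25 RPKM in parental, clone 1 and clone 19 cells, and Epcam 0.0212, 0.0934 and 0.161 RPKM, while Cdx2 and Hnf4a were listed at 0 in all 9 libraries. Krt8 (130, 224 and 206 RPKM) and Krt18 (392, 614 and 581 RPKM) were high, as was Vim (1199, 1100 and 947 RPKM). A hypothesis is that the line expresses a mesothelium-like programme, which may account for keratins without the rest of the epithelial set: 88.9% of the 18 markers (16) reached 1 RPKM in all parental libraries, against 25.6% (11) of the 43 epithelial markers. Without the 4 members seen before, it was 12 of 14 against 8 of 40. The lists share 3 members, Krt8, Krt18 and Krt19, and 1 marker, Wt1, is also among the developmental transcription factors. The values describe the RNA of this line and do not show where it came from.

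Neighbouring genes moved together over long stretches, often in both clones, which were set against the same parental libraries. The strongest in both ran from Prkaca to Orc6 (40 tested genes, median deviation -0.52 in clone 1 and -0.43 in clone 19), and others from Zmynd19 to Rc3h2 in clone 1 (178 genes, -0.36) and from Etl4 to Rc3h2 in clone 19 (193 genes, -0.36). The stretch starting at Rn28s1 was higher (62 genes, 0.49 in clone 1; 91 genes, 0.32 in clone 19). Between the clones the longest ran from 6330415G19Rik to Ypel5 (435 genes, 0.18) and holds the H2 genes. Against parental cells, the stretch from H2-Eb1 to Ptk7 was lower in clone 1 (118 genes, -0.37). These stretches may reflect gains and losses of chromosome parts that parental and cloned cells do not share, which DNA data could test. How many calls they account for remains open: of the 357 genes changed at least 2-fold in both clones, 335 had a set of neighbours in the gene order, and 83.9% of these stayed so after their subtraction.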
